A study of Mus musculus with 18 samples.

How the data were processed

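The samples were 18 arrays of striatum, including the nucleus accumbens, from littermate mice, 1 array per animal. CaMKIV, the product of Camk4, is a calcium and calmodulin dependent kinase that phosphorylates the transcription factor CREB. According to the sample protocols, tissue was dissected from slices of preserved brain, total RNA was purified on columns and checked on chips, and biotin-labelled cRNA was hybridised to Affymetrix arrays. Genotype, treatment and replicate were taken from the sample titles, which gave 3 control and 3 mutant animals injected with saline and 6 control and 6 mutant animals injected with cocaine. The separate description lines named the same genotype and treatment as the title in 0 of 18 samples, and the treatment protocol named 25 mg/kg cocaine for every sample, so the groups rest on the titles. The titles also number the animals, 12 in Arabic numerals (3 per group) and 6 in Roman numerals (cocaine only, 3 per genotype). Each block of 4 consecutive Arabic numbers holds 1 animal of every group. Each block of 2 consecutive Roman numbers holds 1 animal of each genotype.

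The deposited table held log2 expression values for 22690 probe sets in 18 columns, which the authors made with GCRMA in R 2.4.1 according to their processing notes. GCRMA corrects background from probe sequence, equalises the distributions of the arrays and summarises each probe set. Its settings are not given in the sources used here. Values ran from 1.07 to 15.4, and no 2 columns were identical. The equalisation removes any change in total signal between arrays, and the background model compresses dim probe sets, so that a fold change near the floor is underestimated. The number of arrays limits the precision, and no counting depth applies to arrays.

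Probe sets with a log2 value above 4 in at least 3 arrays were kept and the 64 Affymetrix control probe sets were left out, which left 12674 probe sets for 7583 genes. Of these, 11749 carried 1 gene symbol, 406 carried several and 519 none, and a probe set was named by gene only when it carried 1 symbol. A linear model per probe set was fitted with limma 3.58.1 in R 4.3.3, with the 4 groups and the numbering series (Arabic or Roman) as terms, a variance trend with intensity, moderated two-sided tests and Benjamini-Hochberg adjustment, with an adjusted p under 0.05 as the threshold. The fit left 13 residual degrees of freedom, to which moderation added 3.13. There were 7 contrasts, namely cocaine against saline in control mice, in mutant mice and averaged over genotypes, mutant against control after saline, after cocaine and averaged over treatments, and the genotype by cocaine interaction, which is the mutant minus the control cocaine response. All saline arrays are Arabic-numbered, so the averaged cocaine fold change rests on the 12 Arabic-numbered arrays, and the Roman-numbered arrays enter through the spread and through the contrasts that involve genotype.

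Lists of genes were written from textbook knowledge before the data were examined, as were the tests, the naming rule and the first set of alternatives. Of the 25 lists, 21 had at least 5 measured genes and were tested. They cover immediate early transcription factors, activity-induced effectors, CREB target genes, glucocorticoid response genes, feedback phosphatases and sprouty proteins of the MAP kinase pathway, circadian clock genes, heat shock and ER stress genes, the calmodulin kinase and CREB pathway, dopamine and cAMP signalling, neuropeptides, glutamate and GABA receptors, and markers of medium spiny neurons (shared, D1 and D2), GABAergic interneurons, cortical glutamatergic neurons, thalamus and septum, oligodendrocytes, astrocytes, microglia and endothelial cells. Lists for cholinergic interneurons (2 measured genes), choroid plexus (1), midbrain dopamine neurons (4) and red blood cells (1) were too short to test. Lists share genes, and each gene stood as its probe set of highest mean level. Limma's camera compared each list with the other genes at a preset correlation of 0.01, adjusted over the 21 lists of a contrast, and was repeated with a correlation estimated from the arrays. Limma's fry tested whether a list moved, on balance, one way, without comparing it with other genes.

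The genes named are, for each contrast, up to 12 genes with the largest change in each direction among those past the threshold, or the 5 of smallest p where fewer than 5 passed, together with Camk4 in every genotype contrast. From each list they also include up to 4 members past the threshold, or the 2 brightest members where none passed, and any gene with an array far from its group. Single genes and list means were compared between genotypes by exact two-sided permutation of the genotype labels within treatment and numbering series, which allows 8000 relabellings. The size of the cocaine response was compared between genotypes in the same way over the genes past the threshold in the averaged cocaine contrast and over the immediate early factors, with the sign of each gene turned where its averaged response was below 0.

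The same model was tested on simulated data with the spread of these arrays. In the averaged cocaine contrast it recovered 47 of 67 probe sets changed by 0.5 on the log2 scale and 60 of 67 changed by 1. In the interaction it recovered 23 of 67 at 0.5 and 52 of 67 at 1. The noise was drawn independently for each probe set and array, with no outlying array, and the changed probe sets were drawn at random. These rates can therefore exceed those reached in the real arrays, and they do not give the power for genes of large spread.

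Alternatives were a model without the series term, the Arabic-numbered arrays alone, the Roman-numbered arrays alone where both groups had them, blocks of replicate number or of consecutive animal numbers, only the groups compared, other filters, quantile normalization, median centring, array weights, other variance models, an adjusted p under 0.1, the mean of a gene's probe sets and the loss of each array in turn. After the arrays were examined, the difference between the 3' and 5' actin control probe sets was added as a term, alone and together with the loss of mutant cocaine replicate 5. Gene symbols came from the platform annotation and were compared with the RefSeq gene table by Entrez identifier. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.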

Results

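Gene expression was measured in the striatum of control mice and of mice carrying a mutation of Camk4, 1 hour after an injection of saline or of 25 mg/kg cocaine, a psychostimulant that raises extracellular dopamine by blocking its transporter. The series addresses how loss of CaMKIV changes the transcriptional response to cocaine. There were 3 saline and 6 cocaine animals per genotype, and every value below is a log2 GCRMA expression value per probe set, or a difference between such values. After processing, the array medians lay between 4.98 and 5.19.

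The arrays were parted by numbering series, by 1 array that stood apart and, on the second principal component, also by treatment. The first principal component held 41.7% of the variance. Its means were -9.99 ± 7.12 and 28.2 ± 7.75 in the Arabic- and Roman-numbered control cocaine arrays and -14.1 ± 2.71 and -5.33 ± 40.7 in the mutant ones (SD, n = 3 each), where replicate 5 lay at -52.3 and the other 2 Roman-numbered arrays at 19.9 and 16.5. The saline means were 3.89 ± 3.49 in control and -2.60 ± 1.31 in mutant mice (SD, n = 3 each). The Arabic-numbered cocaine means thus lay below them, on the side of replicate 5. The second component held 13.5% of the variance. It ran from 9.13 to 15.3 in the saline arrays and from -0.83 to 6.63 in the Arabic-numbered cocaine arrays. In the Roman-numbered cocaine arrays it ran from -26.8 to -8.29. By their residuals, 12 of 18 arrays were closest to an array of their own block of consecutive animal numbers. For replicate numbers this held for 8 of 18. Residuals correlated by a mean of 0.036 within the consecutive blocks, against -0.099 for any 2 arrays of 1 series. The second value includes pairs of the same group, whose residuals the fit pulls below 0, so the 2 means are not comparable. No chance level was computed for the counts of closest arrays, so these values do not decide on pairing. In limma, 781 probe sets differed between the series, 322 of them higher and 459 lower in the Roman-numbered arrays. Mutant cocaine replicate 5 had a mean correlation of 0.966 with the other arrays, an array weight of 0.0928 and an actin 3' minus 5' difference of 3.59, a measure that rises as RNA shortens. This difference was 1.70 ± 0.13 in the other Roman-numbered arrays (SD, n = 5), 2.38 ± 0.17 in the Arabic-numbered cocaine arrays and 2.20 ± 0.19 in the saline arrays (SD, n = 6 each).

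**Figure D1:**
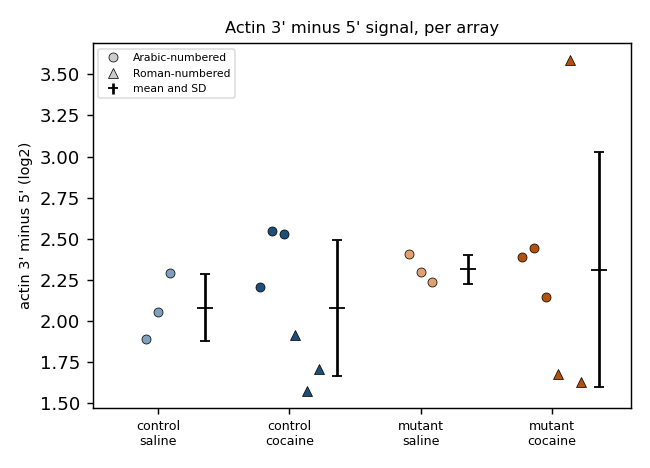
The log2 difference between the 3' and 5' actin control probe sets is plotted for each of the 18 arrays by group, with circles for Arabic- and triangles for Roman-numbered animals and bars for the mean and SD. Mutant cocaine replicate 5 stands at 3.59, while the other 17 arrays lie between 1.57 and 2.55.

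Cocaine raised a set of immediate early genes, the transcripts that neurons induce within an hour of stimulation. Among them, averaged over genotypes, were subunits of the AP-1 transcription factor and zinc finger factors of the Egr family. Fos rose by 4.55 ± 0.48 (log2, SE), a 23.4-fold increase, Fosb by 3.01 ± 0.45 and Junb by 2.57 ± 0.31. Egr2 rose by 3.46 ± 0.39 and Egr4 by 2.30 ± 0.37. Arc, which encodes a protein of the postsynaptic cytoskeleton, rose by 2.96 ± 0.37, a 7.78-fold increase. In all, 28 probe sets passed the threshold in limma, standing for 22 named genes and 1 probe set without a symbol, and every one of them was higher after cocaine.

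Further genes that rose were Btg2, an antiproliferative factor (2.97 ± 0.51), Dusp1, a phosphatase that inactivates MAP kinases (2.10 ± 0.29), the orphan nuclear receptor Nr4a1 (2.08 ± 0.24), the ADP-ribosyltransferase Tiparp (2.08 ± 0.26), the constitutively active receptor Gpr3 (2.05 ± 0.30) and Gadd45b (1.56 ± 0.28). The clock genes Bhlhe40 and Per1 rose by 1.01 ± 0.12 and 0.87 ± 0.15, and the co-chaperone Dnajb5 by 0.89 ± 0.17. The 7 remaining genes, named after their values were seen, were Midn (1.28), Sertad1 (1.21), Gadd45g (0.87), Egr1 (0.72), Chmp1b (0.63), Tob2 (0.60) and Gpr19 (0.49). Adjusted p values in limma ran from 5.53e-04 for Fos to 0.0307 for Dnajb5. A dimmer probe set of Btg2 and both other probe sets of Dnajb5 were also higher but did not pass. For Fos, the lowest cocaine array stood at 7.39 and the highest saline array at 6.52, and for Arc these values were 8.48 and 7.89.

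For cocaine against saline averaged over genotypes, these 28 probe sets also passed, in the same direction, without mutant cocaine replicate 5 (362 probe sets, 95 higher and 267 lower), without mutant cocaine replicate 1 (43, of which 42 were higher) and in the Arabic-numbered arrays alone (430, with 98 higher and 332 lower). The averaged fold change rests on the Arabic-numbered arrays, so leaving out Roman-numbered arrays could change its SE but not its size or direction. The 267 therefore had a median of -0.45 both with and without mutant cocaine replicate 5, and with all arrays none of them passed, as their median SE was 0.261 in place of 0.0958. That array itself lay a median of 1.89 below its group there. Of the 28, 16 passed with blocks of consecutive animal numbers, where the count was 16, and 16 with an ordinary linear model, where it was 17, while 20 passed without control cocaine replicate 2.

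**Figure D2:**
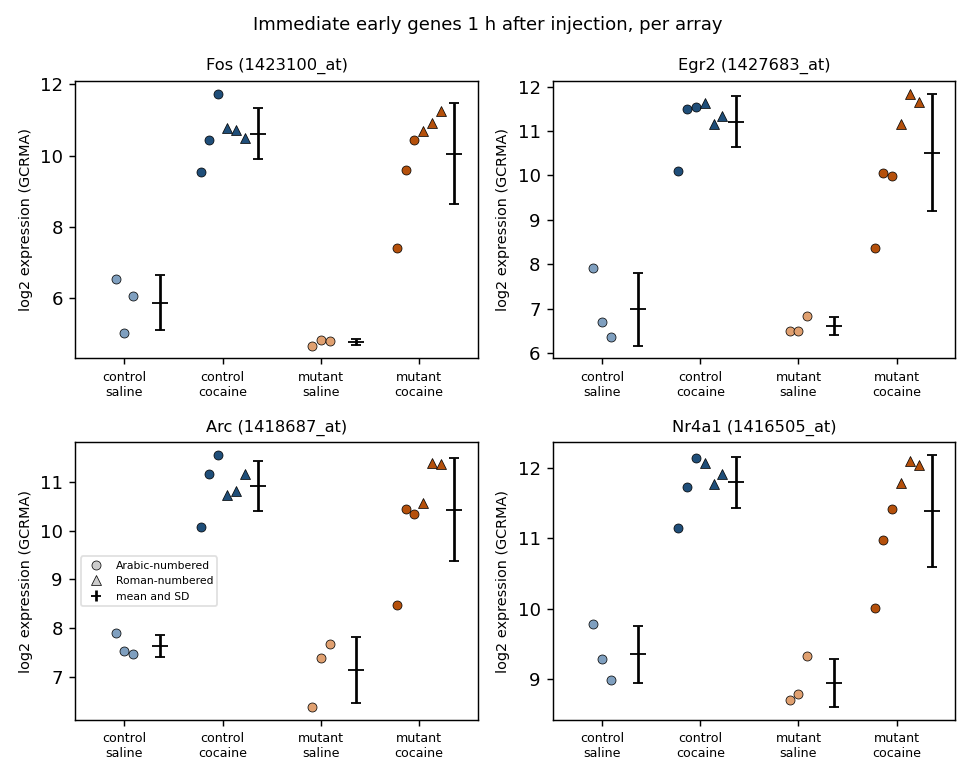
Log2 expression of Fos, Egr2, Arc and Nr4a1 is plotted for each array by group, with circles for Arabic- and triangles for Roman-numbered animals and bars for the mean and SD. For Fos the means are 5.86 and 4.75 after saline and 10.6 and 10.1 after cocaine in control and mutant mice.

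By list, the induction lay in activity-regulated genes. Of the 14 measured immediate early transcription factors, 8 rose (12 adjusted over the list alone), and the list had a median of 1.72. Its camera test had an adjusted p of 1.71e-33 at the preset correlation, with adjusted p = 0.00968 with an estimated correlation. Jun (1.36 ± 0.27) and Klf10 (0.64 ± 0.13) had adjusted p values of 0.0532 and 0.0581, and Nr4a2 was at -0.09 ± 0.46. Of the 20 activity-induced effectors 6 rose (12 adjusted over the list alone), among them Arc, Dusp1 and Tiparp, with a list median of 0.40 and adjusted p = 0.00968 with an estimated correlation. Sgk1 (0.51 ± 0.13), Rgs2 (0.22 ± 0.05) and Homer1 (-0.47 ± 0.26) did not pass over all probe sets.

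A further 5 lists were higher by camera at the preset correlation only. Of 18 CREB target genes 6 rose (7 adjusted over the list alone), namely Fos, Nr4a1, Dusp1, Gadd45b, Per1 and Egr1, all of them activity-regulated. The neuropeptide members Penk (-0.01 ± 0.03), Tac1 (0.04 ± 0.05) and Pdyn (-0.07 ± 0.16) did not pass, the list median was 0.04 and adjusted p = 0.112 with an estimated correlation. Of 18 glucocorticoid response genes 2 rose, Dusp1 and Per1 (7 adjusted over the list alone, median 0.28), while Fkbp5 was at -0.14 ± 0.08 and Tsc22d3 at 0.30 ± 0.09. Of 9 MAP kinase feedback genes 1 rose, Dusp1 (4 adjusted over the list alone), with Dusp6 at 1.01 ± 0.23, and of 15 circadian genes 2 rose, Per1 and Bhlhe40 (2 adjusted over the list alone). For each of these 3 lists adjusted p = 0.0884 with an estimated correlation. Of 14 microglial markers 0 rose, over all probe sets and adjusted over the list alone, with a median of 0.09, Csf1r at 0.11 ± 0.08 and Ctss at 0.04 ± 0.07. The microglial call (adjusted p = 0.0336) gave adjusted p = 0.346 with an estimated correlation. Of these 7 lists, 6 also passed by fry, all but microglia.

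In control mice alone, cocaine raised 12 genes. Fos rose by 4.28 ± 0.63 (SE, adjusted p = 0.0113), Egr2 by 3.62 ± 0.52, Arc by 2.96 ± 0.49, Junb by 2.73 ± 0.40, Dusp1 by 2.26 ± 0.39, Tiparp by 2.23 ± 0.34, Gpr3 by 2.18 ± 0.40 and Nr4a1 by 2.08 ± 0.32. The others were Midn (1.37), Bhlhe40 (1.13), Chmp1b (0.67), a component of the ESCRT machinery, and the orphan receptor Gpr19 (0.60). They came from 14 probe sets in limma, all higher, and 2 further probe sets of Tiparp were higher without passing. The same activity-regulated lists were higher by camera, with 4 of 14 immediate early factors (10 adjusted over the list alone) and 3 of 20 effectors (13 adjusted over the list alone) past the threshold. For both, adjusted p = 0.00886 with an estimated correlation. The other 5 lists called were CREB targets, glucocorticoid response, MAP kinase feedback, circadian clock and endothelial markers, with adjusted p values of 0.109, 0.24, 0.24, 0.0543 and 0.437 with an estimated correlation, and fry called 3 lists. In the first 4 of them 3, 1, 1 and 1 genes rose (6, 3, 4 and 2 adjusted over the list alone). No endothelial marker passed (0 of 9, and 0 adjusted over the list alone).

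The count in control mice depended on the model and on single arrays. It was 0 with blocks of consecutive animal numbers, 1 with an ordinary linear model, 0 with the actin term and without mutant cocaine replicate 5 together, 24 without the series term and 27 with array weights. It was 0 without control cocaine replicate 2 or control saline replicate 3, 1 without control saline replicate 2, 9 without control cocaine replicate 3, 22 without mutant cocaine replicate 1 and 28 without mutant cocaine replicate 5, and 43 (25 higher, 18 lower) in the Arabic-numbered arrays alone.

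In mutant mice cocaine raised Fos, Egr2, Arc, Junb and Nr4a1. Fos rose by 4.82 ± 0.63 (SE, adjusted p = 0.013), Egr2 by 3.29 ± 0.52, Arc by 2.96 ± 0.49, Junb by 2.41 ± 0.40 and Nr4a1 by 2.08 ± 0.32. These 5 genes came from 6 probe sets, all 6 of which were among the 14 called in control mice. Independent calls would share 0.00663, but both contrasts use the same estimate of spread per probe set. Their calls are therefore not independent, and this value understates the sharing to be had by chance. Of the immediate early factors 4 of 14 rose (11 adjusted over the list alone, adjusted p = 0.0645 with an estimated correlation) and of the effectors 1 of 20 (10 adjusted over the list alone, adjusted p = 0.104 with an estimated correlation). CREB targets (2 of 18), glucocorticoid response (0 of 18), MAP kinase feedback (0 of 9) and heat shock and ER stress genes (0 of 15) were also called at the preset correlation, with adjusted p values of 0.316, 0.151, 0.155 and 0.638 with an estimated correlation. Their counts adjusted over the list alone were 6, 4, 2 and 1, and fry called 2 lists.

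The count in mutant mice was 0 with blocks of consecutive animal numbers, with an ordinary linear model or with only the groups compared, 1 with no filter on dim probe sets, 14 without the series term, 11 with array weights and 10 at an adjusted p under 0.1. It was 0 without mutant cocaine replicate 2 or 3 or mutant saline replicate 2 or 3, 1 without mutant cocaine replicate 6 or control cocaine replicate 4 or 6, 3 without control cocaine replicate 2, 21 without mutant cocaine replicate 1 and 26 (13 higher, 13 lower) without mutant cocaine replicate 5. In the Arabic-numbered arrays alone it was 3, all lower and none among the 6.

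The cocaine response did not differ between genotypes by more than the spread of the arrays. Over the 22 responsive genes the mean response was 1.89 in control and 1.77 in mutant mice. The difference, mutant minus control, was -0.13, below 0 in 18 genes, with p = 0.724 in an exact permutation test. Its sign turned without mutant cocaine replicate 1 (0.10) or control cocaine replicate 3 (0.03), with the responsive genes chosen anew in each of these fits. For the 14 immediate early transcription factors the mean difference was -0.08 (exact permutation p = 0.83) with the sign of Nr4a2 turned, the 1 member whose averaged response lay below 0, and 0.02 with no sign turned. Within the Arabic-numbered arrays alone, the response over cocaine-responsive genes chosen from those arrays differed by -0.19 (exact permutation p = 0.305). That set was larger than the 22 genes and included genes lower after cocaine. Array means over the 22 genes there ran from 7.157 to 7.45 after saline and from 8.797 to 9.923 after cocaine in control mice. In mutant mice they ran from 6.982 to 7.137 and from 7.885 to 9.034. The smaller mean rise of the 22 genes in the mutant within that series was not tested. Single genes went both ways, from Fos at 0.54 ± 0.83 (SE) and Tob2 at 0.26 ± 0.19 to Egr2 and Junb, both at -0.33, and Gpr19 at -0.22 ± 0.11.

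Across all probe sets, 0 passed for the genotype by cocaine interaction in limma, with a smallest adjusted p of 0.992, and 0 by an ordinary linear model. An unadjusted p under 0.05 was found for 340 probe sets, where 634 would be expected by chance. The 5 genes of smallest p, none past the threshold, were Cbr4 (-0.36 ± 0.09), Mns1 (1.27 ± 0.34), Ttc19 (-0.24 ± 0.07), the interferon-induced Ifit2 (-0.96 ± 0.27) and Taf1d (0.51 ± 0.15, with another probe set at -0.10). None of the 21 lists passed by camera, by camera with an estimated correlation or by fry. The smallest adjusted p, for astrocyte markers (0 of 14 past, median 0.09), was 0.27. For immediate early factors, with no sign turned, the median was -0.06 and the mean 0.02.

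**Figure D3:**
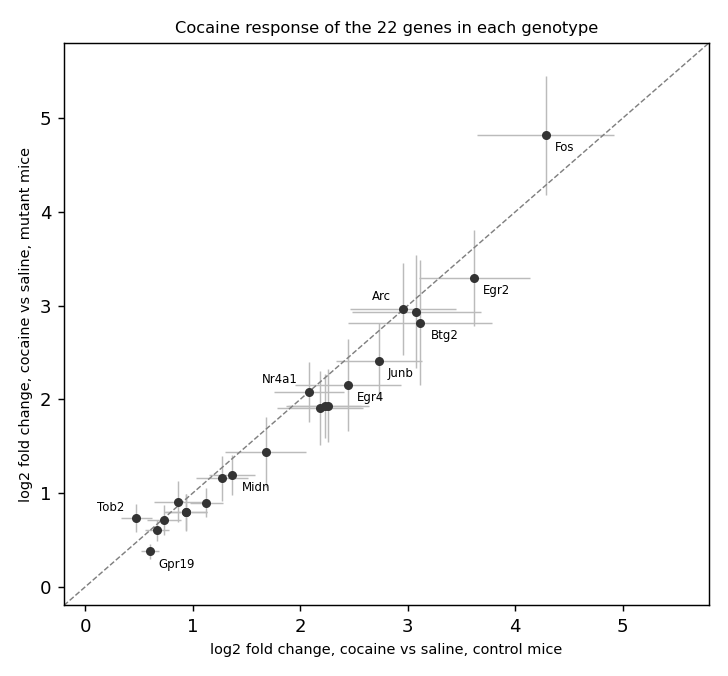
The log2 fold change of the 22 responsive genes after cocaine in mutant mice is plotted against that in control mice, with bars for the SE and a dashed line where both are equal. Of these genes 18 lie below the line, and the mean response is 1.89 in control and 1.77 in mutant mice.

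After saline, no gene passed between mutant and control striatum. Fos was at -1.11 ± 0.68 (SE), Arc at -0.49 ± 0.52 and Nr4a1 at -0.41 ± 0.34. The 5 genes of smallest p were the zinc finger gene Zfp975 (-0.54 ± 0.13), Pacsin1, a protein of synaptic vesicle endocytosis (0.24 ± 0.07), the transcriptional repressor Dr1 (-0.38 ± 0.11), Itm2c (0.14 ± 0.04) and Wnt2 (0.76 ± 0.21). Limma passed 0 probe sets, as did an ordinary linear model, and 350 had an unadjusted p under 0.05.

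By camera at the preset correlation 7 lists differed after saline, none of them with an estimated correlation (adjusted p = 0.301 for astrocyte markers and adjusted p = 0.592 for the other 6) or by fry. At the preset correlation the lists lower in the mutant were immediate early factors (median -0.24), effectors (-0.13), glucocorticoid response (-0.11), heat shock and ER stress (-0.10), MAP kinase feedback (-0.17) and astrocyte markers (-0.08), and endothelial markers were higher (0.15). No member of these lists passed, over all probe sets or adjusted over the list alone. The actin 3' minus 5' difference was 2.08 ± 0.20 in control and 2.31 ± 0.09 in mutant saline arrays (SD, n = 3 each). The lists called fell to 3 without mutant saline replicate 2 and to 2 without control saline replicate 1.

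After cocaine, Spg21 was lower in the mutant by -0.44 ± 0.08 (SE) and Mns1, a gene of cilia and flagella, higher by 1.12 ± 0.20, both with an adjusted p of 0.118. Next came the focal adhesion gene Zyx (0.49 ± 0.11), the homeobox gene Cux1 (0.29 ± 0.06, with another probe set at -0.04) and Rgs2, a regulator of G protein signalling (-0.24 ± 0.05), each with an adjusted p of 0.427. Limma and an ordinary linear model each passed 0 probe sets, although 1470 had an unadjusted p under 0.05 against 634 expected by chance. In the Roman-numbered arrays alone the count was also 0, and 1 passed without mutant cocaine replicate 1, without control cocaine replicate 3 or without control saline replicate 2.

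The lists of activity-induced effectors (median -0.23), CREB targets (-0.20) and immediate early factors (-0.32) were lower in the mutant after cocaine by camera at the preset correlation. With an estimated correlation they had adjusted p = 0.794, adjusted p = 0.8 and adjusted p = 0.8, and fry called 0 lists. Over all probe sets 0 members passed, and adjusted over the list alone 1 effector did, Rgs2. Of the 3 lists, 1 remained called without mutant cocaine replicate 1 or without control cocaine replicate 3. Array means of the immediate early factors, with the sign of Nr4a2 turned, were lower in the mutant in the Arabic-numbered cocaine arrays only. They ran from 6.626 to 7.773 in mutant and from 7.428 to 8.794 in control arrays there. In the Roman-numbered arrays they ran from 7.939 to 8.438 and from 8.006 to 8.186.

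Averaged over treatments, Spg21 (-0.36 ± 0.07), Rgs2 (-0.23 ± 0.05), Pacsin1 (0.20 ± 0.04), the kinesin Kifc2 (0.25 ± 0.05) and Oaz2, an inhibitor of ornithine decarboxylase (-0.16 ± 0.04), had the smallest p between genotypes, with adjusted p values from 0.399 to 0.611. Spg21 was lower in mutant arrays under both treatments, at 8.94 ± 0.01 against 9.21 ± 0.07 after saline (SD, n = 3) and 8.74 ± 0.21 against 9.18 ± 0.10 after cocaine (SD, n = 6). Limma passed 0 probe sets and an ordinary linear model 0, and 904 had an unadjusted p under 0.05. Over the 22 cocaine-responsive genes the mean genotype difference was -0.28, below 0 in 21 of them, with an exact permutation p of 0.0705. It was -0.22 after saline (exact permutation p = 0.1, the smallest that 3 against 3 allows) and -0.35 after cocaine (exact permutation p = 0.29). The value after cocaine pools 2 series that went different ways. Array means over the 22 genes ran from 7.885 to 9.034 in mutant and from 8.797 to 9.923 in control Arabic-numbered cocaine arrays. In the Roman-numbered ones they ran from 9.27 to 9.701 and from 9.339 to 9.533, so the mutant arrays were not lower there.

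Averaged over treatments 6 lists were lower in the mutant at the preset correlation, namely effectors (median -0.21), immediate early factors (-0.33), CREB targets (-0.13), glucocorticoid response (-0.05), heat shock and ER stress (-0.04) and MAP kinase feedback (-0.11). For all 6, adjusted p = 0.4663 with an estimated correlation, and fry called 0 lists. Among their members Rgs2 alone passed adjusted over the list alone, and 0 passed over all probe sets. Brighter members included Nr4a1 (-0.41 ± 0.21), Egr1 (-0.20 ± 0.11), Sgk1 (-0.07 ± 0.11), Dusp1 (-0.33 ± 0.25) and Hsp90aa1 (-0.11 ± 0.04).

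Camk4 itself was lower in mutant striatum. Its brightest probe set was lower by -0.37 on the log2 scale, a level 22.5% below control, with an exact permutation p of 2.5e-04, the smallest the design can give. It stood at 7.65 ± 0.06 in control and 7.30 ± 0.16 in mutant mice after saline (SD, n = 3) and at 7.65 ± 0.10 and 7.27 ± 0.27 after cocaine (SD, n = 6). There the highest mutant array (7.69, Roman-numbered) lay above the lowest control array (7.52, Arabic-numbered). Within each numbering series, every mutant cocaine array lay below every control one. A dimmer probe set was lower by -0.49 (exact permutation p = 5e-04), and by -0.30 without mutant cocaine replicate 5 (exact permutation p = 0.00325). The last of the 3 lay at the floor of the table, with group means between 2.02 and 2.03, and was not tested in limma.

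Over all probe sets Camk4 did not pass in limma, with adjusted p values of 0.611 and 0.679 averaged over treatments. For the interaction its probe sets were at -0.03 ± 0.18 and -0.52 ± 0.53 (SE). The position of the probe sets relative to the mutation is not given in the sources used here, so a remaining signal gives no measure of remaining protein.

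**Figure D4:**
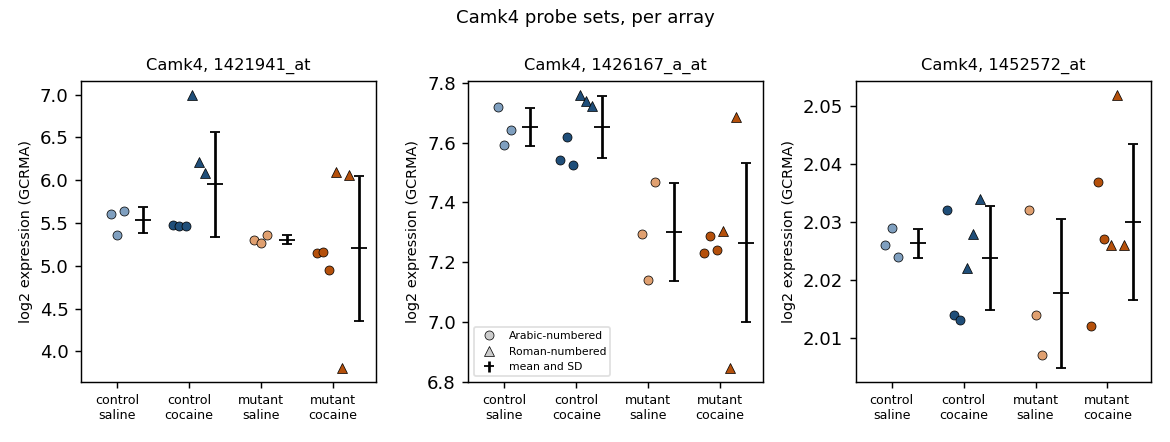
Log2 expression of the 3 Camk4 probe sets is plotted for each array by group on separate scales, with circles for Arabic- and triangles for Roman-numbered animals and bars for the mean and SD. In the middle panel the mutant means are 7.30 and 7.27 and both control means are 7.65, while the probe set in the right panel stays between 2.01 and 2.05 in every array.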

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

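The tests with the actin difference as a term were chosen after the arrays were seen, and the tests of the slope and of single probe sets after the lower probe sets were seen to be low in replicate 5.

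In 200 groups of arrays, single genes or lists, 18 groups (9%) held an array far from the rest of its group by Dixon's test, where chance gives about 1 in 20, and 8 of the 18 lay in mutant cocaine replicate 5. That array had the lowest median of its group, 4.978 against 5.092 for the nearest, and the lowest mean correlation with other arrays, 0.9656. It was also the highest of its group for Csf1r, a microglial receptor (11.08), the astrocyte connexin Gja1 (12.47), Klf9 (14.27) and Ifit2 (5.148), and the lowest for the glutamate receptor subunit Gria2 (11.65) and for Cbr4 (7.978). Arc was lowest in mutant cocaine replicate 1, at 8.479 against 10.34 for the nearest array. Egr2 was lowest in control cocaine replicate 1 (10.1), Dbp in mutant cocaine replicate 4 (12.7) and Dusp8 in control cocaine replicate 4 (9.789), and Penk was highest in mutant cocaine replicate 3 (13.94) and Csf1r in control cocaine replicate 2 (10.92). Among list means, circadian genes were lowest in mutant cocaine replicate 2 (8.602), GABAergic interneuron markers in mutant cocaine replicate 6 (7.373) and oligodendrocyte markers in control cocaine replicate 3 (10.09), and glutamate and GABA receptors were highest in control cocaine replicate 5 (9.841).

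Without mutant cocaine replicate 5, 267 probe sets passed as lower after cocaine, with a median of -0.45 on the log2 scale that was the same with all arrays, where none of them passed because their median SE was 0.261 in place of 0.0958. Adding the actin difference as a term left 107.7% of that median, with 137 of the 267 past the threshold and the median SE at 0.111. Actin differed little between Arabic-numbered cocaine and saline arrays (2.38 against 2.20). The 3' minus 5' difference of the Gapdh control probe sets was not used as a term. It was 0.07 ± 0.08 and 0.06 ± 0.02 in control and mutant Arabic-numbered cocaine arrays (SD, n = 3 each). After saline it was -0.10 ± 0.05 and -0.01 ± 0.04 (SD, n = 3 each), and in replicate 5 it was 0.63. A difference in RNA integrity is therefore not excluded as a cause of the pattern. The same probe sets lay a median of -1.89 from their group in replicate 5, against 0.05 over all probe sets, and the slope of fold change on this deviation over 12312 other probe sets predicts 51.69% of the median, just over the bound of 50% set before it was computed. The 421 other probe sets of the same genes had a median of -0.04, which is 9.826% of that of the lower ones (picked for being low), although 295 of them lay below 0 and 32 passed as lower, and 15.7% of the lower probe sets were the brightest of their gene, against 64.5% of those tested. The lower probe sets were not dim as a set (median level 7.83 against 8.04 for all tested). The 64.5% includes genes with a single tested probe set, whereas 229 of the 248 lower probe sets with 1 gene symbol had others. A shift shared with replicate 5, mostly in probe sets less bright than others of their gene, may therefore account for these falls in part. A fall of the genes' level is not excluded, and an effect of cocaine on particular transcript ends remains open and untested.

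Between the numbering series 781 probe sets differed, by a median of 0.35 on the log2 scale, and 3783 differed without mutant cocaine replicate 5. With the actin difference as a term the median difference of the 781 kept 91.54% of its size and 618 of them passed, in a fit where that replicate weighs most. The Gapdh difference, not used as a term, lay between -0.309 and -0.235 in the other Roman-numbered arrays. In the Arabic-numbered arrays it lay between -0.132 and 0.128. RNA integrity is therefore not excluded as a cause of the series difference. Without that replicate the median kept 89.1%, but the median SE rose from 0.0795 to 0.181, so that 346 of the 3783 passed (396 probe sets in all), and for the others the actin difference and the series are not separated. No biological explanation was tested, since the labels do not say what sets the Roman-numbered animals apart, and a second round of animals, arrays or labelling stays open.

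Activity-induced effectors were lower in mutant than in control mice by a mean of -0.18 over 20 genes. No single array decides this, since the difference kept at least 69% of its size (-0.13 without control cocaine replicate 3). With the actin difference as a term it was 115.2% of its size (-0.21). Mutant cocaine replicate 5 lay far from all other arrays in actin and weighs most in that fit, and leaving it out gave -0.20. The actin term therefore does not decide on RNA integrity among the other arrays. Its exact permutation p was 0.01575, under the bound of 0.05 set in advance, but the list was picked among 21 after their values were seen, and adjusted over those lists p was 0.331. Chance assignment of animals therefore cannot be told apart from an effect of the mutation in these arrays. The hypothesis that loss of CaMKIV may lower the level of activity-induced genes stays open (mean of -0.12 after saline and -0.25 after cocaine), with Rgs2 at -0.23 ± 0.05 (SE) the 1 member past the threshold adjusted over the list alone.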

How the results depend on the processing

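The actin term, alone and with the loss of mutant cocaine replicate 5, and the splits that keep the numbering series were chosen after results were seen, the rest before. The cause of each change below was not tested.

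Outside the loss of single arrays, 99 counts of probe sets stayed within 1.5 times the reported one and 21 did not, and no gene or list past the threshold turned its direction. For cocaine against saline averaged over genotypes (28 probe sets) the count was 67 without the series term, 430 (98 higher, 332 lower) in the Arabic-numbered arrays alone, 103 (60 higher, 43 lower) with array weights, 16 with blocks of consecutive animal numbers, 17 with an ordinary linear model and 224 (51 higher, 173 lower) with the actin term and without mutant cocaine replicate 5 together. For cocaine against saline in control mice (14) it was 24, 43, 27, 0, 1 and 0 in that order. For cocaine against saline in mutant mice (6) it was 14, 3, 11, 0 and 0 under the first 5 of these, 1 with the replicate block, 0 with only the groups compared, 1 with no filter on dim probe sets and 10 at an adjusted p under 0.1. The main model held no term for the blocks of consecutive numbers, although these are balanced over the groups of their series. Mean residual correlation was 0.0045 in replicate blocks and 0.036 in consecutive ones, so pairing is not excluded. Genotype contrasts and the interaction stayed at 0 under these alternatives.

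With an estimated correlation the lists called were 2 for cocaine in control mice, 0 in mutant mice, 2 averaged over genotypes and 0 for mutant against control after saline, after cocaine and averaged over treatments. By fry they were 3, 2, 6, 0, 0 and 0. For mutant against control after saline 4 were called with the mean of a gene's probe sets, and after cocaine 6 in the Arabic-numbered arrays alone. For the interaction 1 was called in the Arabic-numbered arrays alone and 1 with no filter.

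With each array left out in turn, probe sets called ranged from 20 to 362 for cocaine averaged over genotypes, 0 to 28 in control mice, 0 to 26 in mutant mice and 0 to 1 for mutant against control after cocaine, and stayed at 0 in the other contrasts. The averaged count of 43 without mutant cocaine replicate 1 passed the bound of 42 set in advance for more than 1 noisy array by less than the SD of 5.36 between the other counts (a margin added after the value was seen), so spread from replicate 5 alone is not excluded. Lists called ranged from 5 to 10 for the cocaine contrasts, and for genotype from 2 to 8 after saline, 1 to 4 after cocaine and 4 to 8 averaged. For the interaction they were 2 without mutant saline replicate 1 or control saline replicate 3 and 1 without mutant saline replicate 3 or control cocaine replicate 2 or 5. The difference in response size between genotypes, over responsive genes chosen anew in each fit, ranged from -0.26 to 0.10, with exact permutation p from 0.473 to 0.942. Under other alternatives, single genes kept their side of the threshold in 1932 values, lost it in 88 and gained it in 1 (Slc2a1).

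The arrays were also regrouped, and every share given here counts the real split itself. The real number of probe sets was reached by 1 of 84 splits of the control arrays (14, highest other 8). The same held for 1 of 84 of the mutant arrays (6, highest other 5) and 1 of 100 for the averaged contrast (28, highest other 1). In these 3 cases that was the real split alone, but most of the splits put Roman-numbered arrays into saline groups. With the numbering series kept, 2 of 100 splits drawn gave as many for the averaged contrast (highest other 38, the full exchange of saline and Arabic-numbered cocaine labels). This share is under 0.05, which makes chance unlikely there without excluding it. The 20 splits in each genotype, with 1 as large in each (highest other 8 and 0), are too few for a share under 0.05. For lists chance remains a possible source, with 12 of 84, 12 of 84 and 5 of 100 splits as large (7, 6 and 7 real, highest other 9, 8 and 9) and, with the series kept, 5 of 20, 4 of 20 and 11 of 100 (highest other 9, 8 and 11). The counts of 0 for the interaction, for mutant against control after cocaine and averaged over treatments were reached by 100 of 100 splits each, with 1, 0 and 13 as the highest other, and their lists (0, 3 and 6) by 100, 54 and 18 of 100 (highest other 9, 11 and 9). After saline there are 10 splits, too few for a share under 0.05, and 10 reached the 0 probe sets (highest other 1) and 1 the 7 lists (highest other 5). Every split reaches a count of 0 whatever the data, so the shares given for counts of 0 decide nothing.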

Other observations

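The Camk4 neighbour test was chosen before its result was seen; the permutation tests of single lists between genotypes were added after the lists had been tested.

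The cell type composition of the striatal samples showed no list past the threshold beyond those reported. After cocaine, averaged over genotypes, markers shared by medium spiny neurons (median -0.01, adjusted p = 0.551, 0 of 14 past), D1 neurons (0.04, 0.551) and D2 neurons (-0.01, 0.957) did not pass, with Ppp1r1b, the dopamine-regulated phosphatase inhibitor DARPP, at 0.01 ± 0.03 (SE) and the dopamine receptor Drd2 at -0.01 ± 0.07. The same held for GABAergic interneurons (0.04, 0.917), with Sst at 0.03 ± 0.06 and Npy at 0.07 ± 0.11, for cortical neurons (-0.04, 0.888), with Lamp5 at -0.04 ± 0.04, and for thalamus and septum (0.10, 0.551), with Zic1 at 0.35 ± 0.19. Oligodendrocyte (0.03, 0.917), astrocyte (0.02, 0.917) and endothelial markers (0.08, 0.306) did not pass either, with Aldoc at -0.02 ± 0.04 and Slc2a1, the glucose transporter of brain capillaries, at 0.27 ± 0.09. Neuropeptides (0.04, 0.692), dopamine and cAMP signalling (-0.01, 0.732), glutamate and GABA receptors (-0.04, 0.0923), the calmodulin kinase and CREB pathway (0.00, 0.944) and heat shock and ER stress genes (0.07, 0.0807, with Dnajb5 past the threshold) complete the 21 lists.

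Between genotypes, averaged over treatments, all 6 measured D2 neuron markers were higher in the mutant, by a mean of 0.12, with Drd2 at 0.12 ± 0.06 (SE) and Penk at 0.01 ± 0.02. The exact permutation p was 0.0463, or 0.397 adjusted over the 21 lists, and the camera test did not pass (adjusted p = 0.156). All 9 endothelial markers were higher as well, by a mean of 0.13 (exact permutation p = 0.0945, adjusted 0.397), and all of these differences fall within the spread of the arrays once the lists are counted. In the calmodulin kinase and CREB pathway Camk4 was the 1 member of 14 past the threshold adjusted over the list alone, and 0 passed over all probe sets. There Crem, a CREB family repressor and activator, was at -0.32 ± 0.11, Pnck at 0.18 ± 0.08 and Camk2g at 0.14 ± 0.06. Of the other lists, shared medium spiny neuron markers had a median of 0.05 (adjusted p = 0.156), oligodendrocytes 0.08 (0.156), astrocytes -0.04 (0.0513) and microglia -0.02 (0.115).

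Genes close to a targeted locus can differ between genotypes because they keep the sequence of the strain in which the mutation was made. This hypothesis was tested on the 83 measured genes within 10 Mb of Camk4 on chromosome 18. Of these, 4 (4.819%) had an unadjusted p under 0.05 between genotypes, namely Nrep, Ndfip1, Fam13b and Sil1, against a median of 6.67% over 7570 windows of equal length, 31.5% of which had a lower share. The neighbours of Camk4 thus showed no excess of differences.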
